A study of Mus musculus with 2 samples.

How the data were processed

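Self-transcribing active regulatory region sequencing (STARR-seq) was run in mouse naive CD4 T cells that had been activated in culture. In this reporter assay a library of DNA fragments is placed in the transcribed part of a plasmid, so that a fragment with enhancer activity raises the amount of its own RNA. Per the labels, the cells came from strain C57BL/6NJ, carried the plasmids as episomes after transient transfection, and were treated for 3 days with antibodies to CD3e and CD28, antibodies to interleukin-4 and interferon-gamma, and interleukin-2. The series held 1 group of 2 biological replicates, whose labels name separate biosamples of the same donor record. The labels give a library size range of 200 to 400 and 30 µg of starting nucleic acid for both replicates.

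The measurement was 1 deposited list of elements for both replicates together, with coordinates on build mm10 per the labels. The deposited effect of each element was taken as a log2 value, although neither the log base nor the direction of the contrast is given in the sources used here. The authors also deposited a p-value and an adjusted p-value per element on the linear scale. The adjusted p-values equalled a Benjamini-Hochberg adjustment of the p-values over an implied 114722 tests, within 0.1 percent, in all 10531 listed elements. The largest adjusted p-value was 0.01, so the list held 9.18% of the implied tests, and the regions tested but not listed were not analysed here. The last column, deposited under the place of a peak summit, equalled the element's width in every listed element. Starts lay on a grid of 25 bp and were counted from 1. The aligner, the element caller and the input library were not given in the sources used here. No per-replicate value, read count, input coverage or strand was in the list used here, so the depth is unknown, the spread between replicates could not be computed, and no interval below covers it. How the 2 replicates entered the authors' p-values was not given in the sources used here.

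Elements with an effect above 0 are called positive and the others negative. Positive elements are likely those with more reporter RNA than the input plasmid predicts, but this reading of the sign was not stated in any source used here. Annotation and sequence came from GENCODE M21 basic transcripts and the GRCm38.p6 genome, the assembly of mm10. The 10 elements on unplaced scaffolds were counted but not annotated, which left 10521. An element was a promoter element when its midpoint lay within 1000 bp of a transcription start site (TSS) of any gene type, and otherwise exonic, intronic or intergenic by its midpoint. Classes were compared between positive and negative elements by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 4 classes, and each was set beside 1000 random placements of the same widths on the same chromosomes. Differences of medians were tested by two-sided permutation with 100000 resamples, or 10000 in the alternatives. Medians of effects carry binomial order-statistic intervals, and shares carry exact Clopper-Pearson intervals, at 95%.

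For 32 motifs fixed before the data were examined, at least 1 match to the consensus on either strand was counted. Elements were compared with each other and with random windows matched on width and on GC content in bins of 2 percentage points, by Fisher's exact test, two-sided, adjusted over all motifs and 3 contrasts. The windows were not matched on promoter position. Each element was assigned to the protein-coding gene with the nearest TSS within 100000 bp. For 14 gene lists fixed before the data were examined, the number of genes with an assigned element was compared with 10000 random lists matched on the decile of the territory nearest to each gene, one-sided, adjusted over lists and directions. Nearness does not show that an element acts on the gene. Of 376 list genes, 369 were found in the annotation. All tests run across elements or genes of 1 call set, and elements are not replicates of the experiment. Placements, windows and random lists were drawn from whole chromosomes or all protein-coding genes, since the tested regions were not known. An excess over them can come from which regions were tested, so it does not by itself show activity. A call means an adjusted p of at most 0.05.

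The elements named were the 10 with the largest and the 10 with the most negative effect, the 3 members of each list with the largest absolute effect, and the 5 genes with the most assigned elements, except that 1 list member is not reported here. Motifs were named as the 5 largest odds ratios each way per contrast among those called. HNF4 and REST were also named, whether called or not. A copy was a match of at least 95% identity over the element elsewhere in the genome, found with minimap2 2.31. Sequences were read with samtools 1.23.1 and pysam 0.24.0, and statistics were computed in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1. The steps were tested on simulated data. With a motif planted in 1 of 5 windows, 2 of 96 tests were called, both of that motif, and 0 were called with nothing planted. A list given extra elements was recovered in 20 of 20 runs, with 0 calls among 280 tests of unaltered runs. The simulated genes were drawn in proportion to territory, the quantity matched, so these runs cover no other bias, such as promoter GC. The median test called 5.1% of 10000 simulated pairs with no shift. Its simulated values were independent, so it does not cover elements that share a gene.

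Alternatives covered stricter thresholds, effect size, chromosomes, the promoter window, gene types, the motif background, the part of the element searched and the distance to a TSS. With the nearest TSS of any gene type, the random lists were also drawn from genes of any type. Alternatives on copy number, width, promoter GC and GC bins were chosen after seeing the data. A change of sign with no call on either side was not counted as a reversal.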

Results

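STARR-seq of activated naive mouse CD4 T cells gave 1 list of elements from 2 biological replicates of 1 group. The labels name no second condition, so the comparisons lie within the list, between elements of opposite sign. The list held 10531 elements, of which 5407 (51.3%) had a positive and 5124 a negative effect. Effects and p-values are those the authors deposited, and the effect is taken as log2. The median effect was 1.36 (95% interval 1.34 to 1.38) over positive elements and -1.44 (-1.46 to -1.42) over negative elements. An absolute effect of at least 2 was listed for 1355 positive and 1045 negative elements, and one of at least 4 for 177 positive and 11 negative elements. Positive elements were narrower, with a median width of 475 bp against 800 bp. No replicate values were analysed here, so these intervals cover the spread between elements only.

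**Figure D1:**
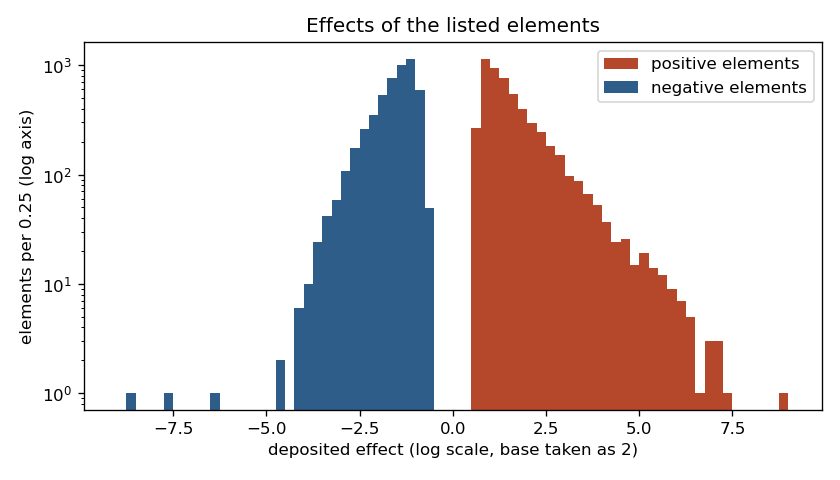
Histogram of the deposited effect (x axis, log scale with the base taken as 2) of the 10521 elements on placed chromosomes, with the number of elements per bin on a log axis. No element lies near 0, since the smallest absolute effect listed was 0.51, and the positive side extends further, with 177 elements at 4 or more against 11 on the negative side.

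The largest positive effects lay mostly at repeated loci. The largest, 8.89, was listed for an intergenic element on chromosome 17 (21477701 to 21478600), 10848 bp from the TSS of Zfp53, a zinc finger gene, with 79.3% of its bases masked as repeats. The next were 7.28 on chromosome 7 (8092751 to 8093100), nearest to Vmn2r41 at 68729 bp, and 7.23 on chromosome 14 (7658126 to 7658225), nearest to Gm10128 at 14203 bp. An element 62 bp from the TSS of Gvin1, a gene of the interferon-inducible GTPase family, had an effect of 7.13 on chromosome 7 (106215301 to 106215475). The rest of the 10 were nearest to Gm5861, Unc93a2, Gm3636, Slc19a2, Gm2237 and Gm10553. Of these 10 elements, 9 had another near-identical copy in the genome, the element near Zfp53 being the exception.

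The most negative effects lay mostly at GC-rich promoters. The lowest, -8.53, was an intergenic element on chromosome 10 (11491951 to 11492275), 148709 bp from Epm2a. The element at the promoter of Eya2 on chromosome 2 (165595126 to 165595300), 181 bp from its TSS in the untranslated region, had -7.55 at a GC content of 77.7%. An intronic element of 50 bp nearest to Clip4 had -6.26. Those at the promoters of Chn1 (-4.70), Zdhhc18 (-4.57), Slc4a7 (-4.21), Rai2 (-4.18), Pcbp4 (-4.17), Zbtb39 (-4.13) and Klhl23 (-4.07) followed. Of the 10, 1 had another copy, the element nearest to Clip4.

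Negative elements were mainly promoter elements and positive elements were mainly distal. Promoter elements made up 84.8% of negative elements (95% interval 83.8 to 85.7) and 20.02% of positive elements (18.96 to 21.1). Random placements gave 4.52% and 4.49%, so both directions lay above placement, by 18.8 and 4.46 times. Placements fell anywhere on the chromosomes, so a difference from placement may reflect which regions were tested. Introns held 39.0% of positive and 6.85% of negative elements, and intergenic sequence held 37.7% and 5.51%. Random placements gave 40.8% and 41.0% in introns and 51.6% and 51.3% in intergenic sequence, so both directions lay below placement in both classes, negative elements by far more (0.167 and 0.107 of placement) than positive elements (0.956 and 0.73). The smallest of these differences, that of positive elements in introns, had a two-sided permutation p of 0.016 over the 1000 placements, not adjusted. The median distance to the nearest protein-coding TSS was 21392 bp for positive and 189 bp for negative elements. The odds ratio of positive over negative was 0.045 for promoters (0.041 to 0.050), 8.70 for introns (7.71 to 9.82) and 10.4 for intergenic sequence (9.09 to 11.8), all 3 called by Fisher's exact test. Exons did not pass Fisher's exact test (3.28% against 2.87%, adjusted p = 0.236), and this call changed with the promoter window. Pooled over GC bins, an alternative chosen after seeing the data, the odds ratio of promoters for negative over positive elements fell from 22.2 to 1.69 (1.42 to 2.00), the intergenic odds ratio of positive over negative fell to 1.72 (1.44 to 2.06), and the interval of the intron odds ratio included 1 (0.999, 0.833 to 1.20).

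Promoter elements had somewhat smaller positive and larger negative effects. The median positive effect was 1.29 at promoters (1081 elements) and 1.37 elsewhere (4318), with an adjusted p of 0.00454 by permutation. The median negative effect was -1.47 at promoters (4342) and -1.29 elsewhere (780), with an adjusted p of 2e-05 by permutation, from the smallest p that 100000 permutations can give. The positive difference was lost at an adjusted p of at most 0.001, and both were lost among the 50% of elements with the smallest p.

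Direction followed the GC content of the element. The median GC content was 47.7% over positive elements and 67.6% over negative elements, against 41.7% in random placements, a difference of -19.9 percentage points (p = 1e-05, the smallest 100000 permutations can give). CpG dinucleotides numbered 13.3 per kb in positive and 91.6 per kb in negative elements at the median. Of elements at 45 to 50% GC, 94.96% were positive (93.9 to 95.9), against 62.7% at 55 to 60%, 21.6% at 60 to 65% and 1.30% at 70 to 75%. Promoter elements followed the same course, with 91.9% positive at 45 to 50% GC (87.0 to 95.4, 186 elements) and 3.96% at 65 to 70%. At 60 to 65% GC, 19.5% of promoter and 34.1% of other elements were positive.

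**Figure D2:**
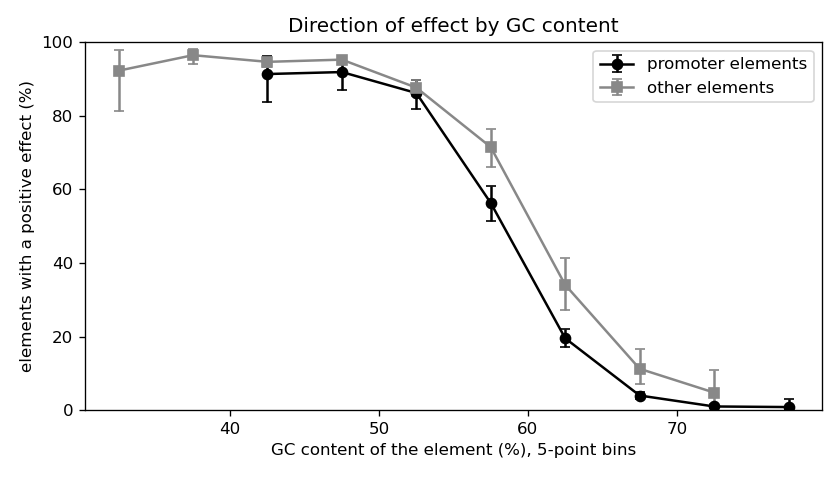
Share of elements with a positive effect (y axis, percent) by GC content in bins of 5 points (x axis), for promoter and other elements, with exact 95% intervals as bars and bins of at least 20 elements. Both curves fall between 50 and 70% GC, from 86.2% to 3.96% at promoters and from 87.7% to 11.2% elsewhere.

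Motifs of activation and interferon factors were frequent in positive elements. AP-1, the site of the FOS, JUN and BATF factors induced by T cell activation, was matched in 30.1% of positive elements and 7.43% of their GC-matched windows (odds ratio 5.36, 4.77 to 6.03, adjusted p = 2.5e-209, Fisher's exact test). The interferon-stimulated response element (ISRE), bound by IRF factors, was matched in 19.7% against 4.70% (4.96, 4.30 to 5.72, adjusted p = 2.1e-131, Fisher's exact test). The composite site of BATF with IRF had an odds ratio of 11.5 (4.61 to 28.7), though it was matched in only 1.06% of positive elements. The cyclic AMP response element (CRE) had 9.87 (6.47 to 15.1) and NRF1 had 3.91 (2.25 to 6.78). In all, 21 of 32 motifs were more frequent in positive elements than in the windows, and 1, the ZEB E-box, was less frequent (29.1% against 33.9%, odds ratio 0.799). Promoters made up 20.02% of positive elements and 8.95% of these windows. The windows were drawn from whole chromosomes, so an excess may also reflect which regions were tested. Neither HNF4 (0.706, adjusted p = 0.233) nor REST (adjusted p = 1) was called by Fisher's exact test. REST was matched in only 3 positive elements and 2 windows, too few to show a difference.

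Fewer motifs were more frequent in negative elements than in their GC-matched windows. Promoters made up 84.8% of negative elements and 62.4% of these windows. The counts of motifs in the 2 directions thus come from backgrounds that differ in promoter share. CTCF, the insulator factor, had an odds ratio of 3.93 (2.63 to 5.89), POU 2.79, ETS 2.01, AP-1 1.95 and NRF1 1.92, among 13 motifs that were more frequent. The 3 less frequent motifs were YY1 (0.456), NFKB (0.875) and the CACCC site of KLF factors (0.885). Without promoter elements, 5 motifs were more frequent and ETS changed sign without a call (log2 odds ratio -0.42). Promoter windows were kept in that background, so these changes cannot be told apart from the promoter share of the windows. With flanking windows, which are poorer in GC, as background, 15 motifs were less frequent in negative elements and AP-1 and POU turned to that side, while YY1, NFKB and KLF CACCC turned to the other.

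Set directly against each other, positive elements held BATF-IRF (odds ratio 10.9), ISRE (5.70), AP-1 (4.54), TATA (3.52) and NFAT (2.58) more often. Negative elements held ZBTB33 (0.050), SP/KLF (0.058), EGR (0.077), NRF1 (0.160) and E2F (0.238) sites more often, the SP/KLF site being matched in 70.1% of negative and 11.9% of positive elements. This contrast is not matched on width or GC content. Negative elements were wider (median 800 bp against 475 bp) and richer in GC (median 67.6% against 47.7%). Against GC-matched windows, Fisher's exact test did not call ZBTB33 (1.27), EGR (1.06) or E2F (0.859) in negative elements. It did call SP/KLF (1.67) and NRF1 (1.92) there. In positive elements it called BATF-IRF, ISRE, AP-1 and NFAT (1.24) but not TATA (1.06). In the central 200 bp of each element, no motif named for the direct contrast lost its call or changed sign. REST was matched in 3 positive and 11 negative elements (0.258, adjusted p = 0.0467, Fisher's exact test), a call lost at a deposited adjusted p of at most 0.001 (adjusted p = 0.722) and turned in sign without promoter elements (log2 odds ratio 0.34). Within 55 to 65% GC, an alternative chosen after seeing the data, the log2 odds ratio was 0.93 for ISRE (adjusted p = 0.000233), 0.52 for AP-1 (adjusted p = 0.0156) and -1.56 for SP/KLF (adjusted p = 1.1e-28), by Fisher's exact test. BATF-IRF, NRF1 and E2F were not called there, and NFAT, TATA and REST changed sign without a call.

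**Figure D3:**
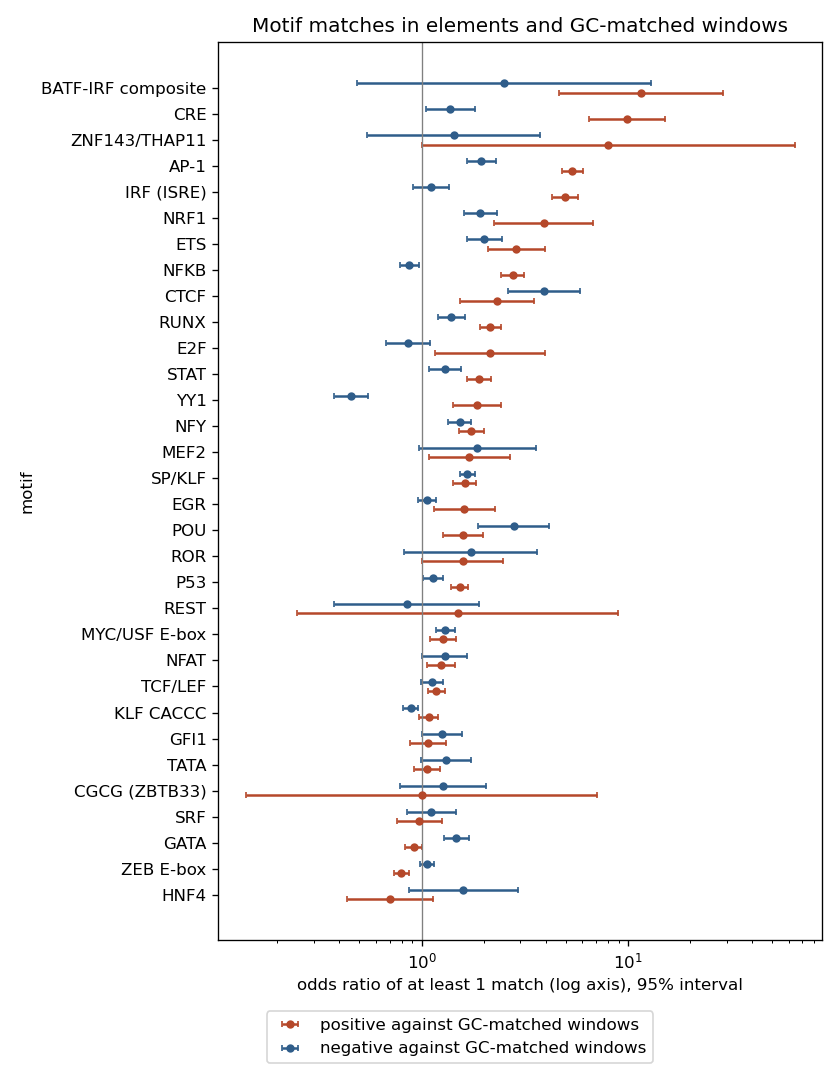
Odds ratio of at least 1 match per motif (x axis, log scale) in positive and in negative elements against their GC-matched windows, with 95% intervals as bars. AP-1 and ISRE stand at 5.36 and 4.96 in positive elements, and the largest value in negative elements is 3.93 for CTCF.

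Genes of T cell activation and of the interferon response carried positive elements more often than matched random genes. The random genes came from all 21917 protein-coding genes, since the tested regions were not known. An excess may therefore reflect which regions were tested as well as their effects. Of 43 activation and costimulation genes, 33 had a positive element against 8.21 expected (adjusted permutation p = 7e-04, from the smallest p that 10000 random lists can give). The largest effects in this list were 3.42 in an intron of Lag3, an inhibitory receptor (chromosome 6, 124907826 to 124908125), and 2.93 in an intron nearest to Tigit, another inhibitory receptor (chromosome 16, 43602576 to 43602900). The element nearest to Egr1, an immediate early factor, was negative at -2.59 and lay 26256 bp away. Of 29 interferon response genes, 19 had a positive element against 3.67 expected (adjusted permutation p = 7e-04). A negative element was assigned to 1 of them against 4.84 expected. That shortfall was not called (adjusted one-sided permutation p = 0.318). Promoter elements made up 19 of the 25 positive elements of this list, and without promoter elements the excess was 1.51 times and not called (adjusted permutation p = 0.553). The largest were at the promoters of Ifit3 (3.72, chromosome 19, 34583051 to 34583500, which has another copy), Ifih1 (2.98, chromosome 2, 62645651 to 62646500) and Oasl2 (2.90, chromosome 5, 114897051 to 114897800), which encode antiviral proteins.

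The other T cell lists were mostly above matched random lists as well, with the same limit. Genes of the IL-2 and STAT5 response had a positive element in 16 of 23 cases against 3.89 expected (adjusted permutation p = 7e-04), with 3.53 in an intron of Cdk6, whose element has another copy, 2.42 near Ccnd2 and 1.86 in Bcl2l1, a survival gene. T lineage transcription factors had one in 16 of 26 cases against 5.75 (adjusted permutation p = 7e-04), led by Runx1 (2.55), Ets2 (2.51) and Fli1 (2.00). Genes of naive and quiescent T cells had one in 14 of 25 cases against 5.25 (adjusted permutation p = 0.00112), where Klf3 carried a negative element of -2.84 at its promoter and Slfn2 and Ccr7 had positive elements of 2.73 and 2.16. Helper subset genes had one in 14 of 34 cases against 6.83 (adjusted permutation p = 0.0136), with Maf at 2.505, Ikzf2 at -2.45 and Stat4 at 2.30. T cell receptor signalling genes had one in 10 of 27 cases against 5.03, which was not called (adjusted permutation p = 0.0637), with Sla2 at 2.86, Fyn at 2.11 and Vav1 at -1.51.

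Lists of general functions and of other cell types were not called for positive elements. Glycolysis had one in 6 of 21 cases against 3.37 expected, and the cell cycle in 4 of 30 against 3.74. Ribosomal proteins and translation had one in 6 of 36 cases against 3.52. Among markers of other cells, 2 of 19 B cell genes had one against 2.59 expected, and 2 of 19 myeloid genes against 2.94. Hepatocyte genes had one in 3 of 20 cases against 3.09, and neuron genes in 1 of 22 against 4.72. Pdk1 (3.30), Hk1 (2.53) and Pfkl (1.71) led glycolysis, and Ccne2 (3.99), Ccne1 (3.67) and Tyms (2.89) led the cell cycle. Rpl3 (2.05), Eef1a1 (1.38) and Tpt1 (-2.16) had the largest effects among translation genes. The effects of the markers named within each list were Pax5 (-2.65), Cr2 (-1.99, whose element has another copy) and Ebf1 (1.34) for B cells, Cebpb (1.79) and Fcgr1 (1.01) for myeloid cells, G6pc (1.82), Pck1 (1.38) and Apoa1 (0.90) for hepatocytes, and Gad2 (3.69) and Map2 (-1.91) for neurons. The element nearest to Gad2 matched the mitochondrial genome.

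For negative elements, the T lineage transcription factors were the 1 list called, with 15 of 26 genes against 6.67 expected (adjusted permutation p = 0.0028). That call was lost at stricter p-values and with random lists matched on promoter GC (adjusted permutation p = 0.0542), an alternative chosen after seeing the data. Within 500000 bp, 2 lists were called for negative elements. With the nearest TSS of any gene type 5 were, but there the random lists also held genes of any type. Those 5 calls therefore do not show the effect of the assignment alone. Positive elements near interferon genes had a median effect of 1.89 (25 elements) against 1.33 near other genes (adjusted p = 0.0421, permutation test), and those near cell cycle genes had 2.62 (7 elements, adjusted p = 0.0421, permutation test). Both calls were lost at stricter p-values and among elements of at least 200 bp. There the cell cycle difference was 1.12 to 1.24, against 1.28 as reported, and the interferon difference was 0.25 to 0.53, against 0.56. The 7 cell cycle elements lay near 4 genes and the 25 interferon elements near 19, while the permutation treated elements as independent. The cell cycle median was the effect of a 75 bp element near Ccne2 that has another copy.

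**Figure D4:**
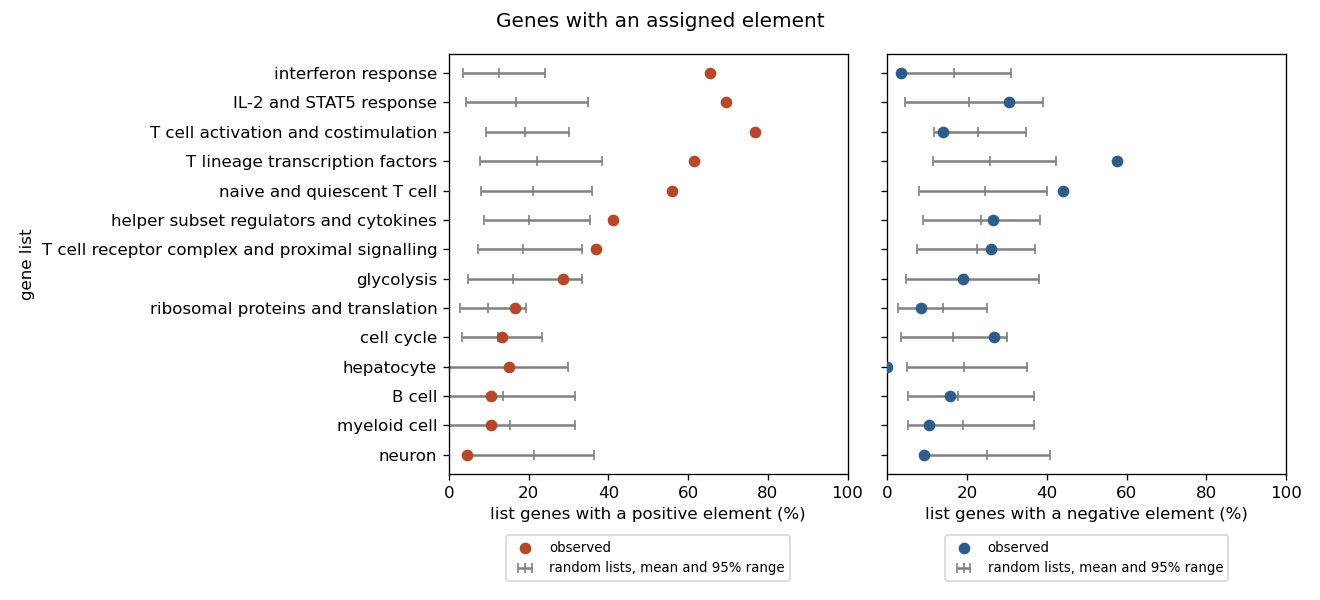
Share of each list's genes (x axis, percent) with an assigned positive element and with an assigned negative element, beside the mean and 95% range of 10000 random lists matched on territory. Of the interferon genes, 19 of 29 have a positive element against 3.67 expected, and 1 has a negative element against 4.84 expected.

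The genes with the most assigned elements were Dynlt1b and Sfi1 with 8 each, all positive, and Bach2, Dnmt3a and Pls3 with 7 each. Bach2, a repressor that keeps T cells quiescent, had 5 positive and 2 negative elements, the latter 216 and 800 bp from a TSS. Dnmt3a, a DNA methyltransferase, had 1 positive and 6 negative elements. All 8 elements near Dynlt1b and all 7 near Pls3 had another near-identical copy, as did 2 of the 8 near Sfi1 and 0 of those near Bach2 and Dnmt3a. Elements were densest on chromosome 11, at 6.00 per Mb, and sparsest on chromosomes X, at 1.31 per Mb, and Y, at 0.044 per Mb. The share of positive elements per autosome ran from 43.0% on chromosome 4 (39.3 to 46.8) to 61.2% on chromosome 13 (56.6 to 65.6).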

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

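A signal lay in part of the list that most comparisons did not use. The 10 elements on unplaced scaffolds entered the counts and effect sizes but no comparison that needs the annotation. Of these, 8 were positive and 2 negative. A single scaffold held 5 of them, all positive, with effects from 0.72 to 1.10.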

How the results depend on the processing

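Alternatives on copy number, width, promoter GC and GC bins were chosen after seeing the data. The depth and the replicate spread are unknown. An input count filter, effects recomputed from counts and leaving out each replicate were not run, since the list used here has no counts and no column per replicate; effect by input coverage and strand of elements were not analysed for the same reason. Merging overlapping or book-ended elements changed nothing, as there were 0 of either (smallest gap 25 bp); merging across gaps was not run. No paired analysis was possible because the series has 1 group. The cause of the changes below was not tested, except that stricter thresholds and subsets hold fewer elements.

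At an adjusted p of at most 0.001 there were 3530 positive and 3070 negative elements with medians of 1.58 and -1.69, chromosomes 11 and X held 3.60 and 0.748 elements per Mb, the positive promoter difference was -0.044, 0 lists were called for negative elements, the T lineage excess was 1.57 times, and the effect differences were 1.21 for the cell cycle and 0.36 for interferon. Among the 50% of elements with the smallest p the same values were 2907 and 2359, 1.69 and -1.81, 2.86 and 0.555, -0.019 (-0.11 for negative elements), 0, 1.40, 1.24 and 0.25, and the exon log2 odds ratio of 0.65 was called. Single-copy elements had a positive median of 1.28. Elements of at least 200 bp had 1.32, with differences of 1.12 for the cell cycle and 0.53 for interferon. The exon log2 odds ratio turned to -0.48 with a promoter window of 500 bp and was called at 0.46 with 2000 bp, and pooled over GC bins the intron value was -0.0021.

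Without promoter elements, 5 motifs were more and 1 less frequent in negative elements than in windows, the interferon excess was 1.51 times, and 7 of 96 motif tests reversed, among the motifs named ETS (log2 odds ratio -0.42) and NFKB (0.24) in negative elements and for REST (0.34) between directions. Promoter windows were not left out of the background in this alternative. With flanking windows, 15 motifs were less frequent in negative and 2 in positive elements, and 23 of 64 motif tests reversed, among the motifs named, in negative elements, AP-1 (-0.46), POU (-1.40), HNF4 (-0.90), NFKB (1.26), KLF CACCC (0.94), YY1 (3.32) and REST (3.46). In the central 200 bp, 2 motifs were less frequent in positive elements, and 3 of 96 tests reversed, of motifs not named for those contrasts. At 55 to 65% GC, 4 motifs were more and 6 less frequent in positive than in negative elements, and 10 of 32 tests reversed, among the motifs named NFAT (-0.096), TATA (-0.46) and REST (0.78). Lists called for negative elements numbered 2 within 500000 bp and 5 with any gene type, where the random lists also held genes of any type. With random lists matched on promoter GC they numbered 0, and the T lineage excess was 1.57 times.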

Other observations

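All tests in this part were chosen after the patterns were seen, and the outcomes of 2 of them, on repeat copies and on element width, had not been seen when their predictions were written. No biological explanation was tested, since the series has 1 group.

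The negative effects lay at promoters, with an odds ratio of 22.2 against positive elements. GC content as the whole cause is argued against by the pooled odds ratio of 1.69 (1.42 to 2.00) within GC bins, although bins of 2 points leave some difference in GC content inside each bin. Promoter position as the whole cause is argued against by promoter elements under 50% GC, of which 91.6% (87.9 to 94.5, 298 elements) were positive. These lay near a TSS of any gene type, and the share was not computed for protein-coding promoters alone. The log odds ratio within bins was 16.9% of the crude one, so GC content may account for the larger part of the promoter excess. CpG dinucleotides (91.6 per kb in negative against 13.3 per kb in positive elements at the median) differed as well and were not separated from GC content. Whether GC content itself acts thus stays open. If it does, loss of GC-rich fragments in the library and repression cannot be told apart, since the input library was not analysed here.

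ISRE matches were frequent in positive elements. Reads from annotated exons of the cells' own interferon-induced transcripts are argued against as the whole cause by elements far from them. With midpoints in no exon and over 10000 bp from any TSS, the odds ratio against GC-matched windows was 4.58 (3.74 to 5.60, 2495 elements). Such elements can lie in introns, so reads from unspliced or unannotated transcripts of the cells are not excluded. Repeat copies are argued against by single-copy elements with under 10% repeat bases, at 4.46 (3.55 to 5.61, 2186 elements). A candidate explanation that stays open is an interferon response of the cells to transfected DNA, which no untransfected or untreated sample analysed here can test.

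The largest positive effects lay at repeated loci. The share of positive elements with another copy rose from 0.357% at effects under 1 to 43.9% at 3 to 4 and 82.7% at 5 or more. The odds ratio of another copy at an effect of at least 3 was 16.1 (13.0 to 19.8), which restates the pattern and does not test its cause. Reads shared between near-identical copies stay open, since the list used here has no read counts. Short elements alone are argued against by elements of 400 to 600 bp, where it was 23.6 (14.6 to 38.1). Elements that matched the mitochondrial genome were nearest to Col19a1 (6.12), Ccnh (4.33) and Gad2 (3.69).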
